A study of Mus musculus with 5 samples.

How the data were processed

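Polyadenylated RNA of splenic dendritic cells from C57BL/6 mice was sequenced in 5 libraries, 1 each for mock at 0 h, 4 h and 8 h and for CSGG at 4 h and 8 h, and groups follow the agent and time in the labels. Per the labels' protocols, RNA was extracted with Trizol, treated with DNase and made into libraries with a stranded mRNA kit. The submitters' processing notes name FastQC, cutadapt, TopHat2, TopHat, Bowtie2, Bowtie, Cufflinks and Cuffdiff, with no versions or roles, and the mouse build mm10. The deposited values of the authors are FPKM per gene symbol, that is fragments scaled for transcript length and library size, 1 file per library. The file headers name only the gene and the sample, so the unit was read from the values and from the tools in the notes. The gene annotation, the strand setting of the counting and any further scaling between libraries are not given in the sources used here. Without the strand setting, overlapping and antisense genes cannot be separated, and near-identical copies (Hspa1a and Hspa1b, hemoglobin, Ifit and histone genes) can exchange reads. FPKM of transcripts shorter than a sequenced fragment is unreliable, because the length correction becomes extreme.

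Each file lists 26665 symbols, with 0 repeated; 25 symbols had been turned into dates, 17 of them among the analysed genes, and were kept as they stood but matched to no gene, and 3 symbols are joined names. From the deposited FPKM, log2(FPKM + 1) was computed, and the 11381 genes with a mean of at least 1 FPKM over the 5 libraries were analysed with no further scaling. Ratios compare CSGG with mock at 4 h and at 8 h, and mock at 4 h and 8 h with mock at 0 h and with each other, 5 comparisons in all. With 1 library per group the difference at either time cannot be tested, so genes were counted where the log2 ratio reached 1 in either direction. Overlap between the times is given beside the number expected of independent lists.

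The groups, comparisons, size rule, naming rule and 26 gene lists were fixed before the data were examined. A list's median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression, and called higher or lower outside the 2.5 and 97.5 percentiles. This describes the libraries and is not a test of the conditions. The lists cover proinflammatory cytokines, chemokines, NF-kB targets, interferon-stimulated genes, tolerogenic genes, maturation, MHC class I and II, pattern receptors, markers of type 1, type 2 and plasmacytoid dendritic cells, B, T and NK cells, monocytes and macrophages, neutrophils, erythroid cells and platelets, and glycolysis, oxidative phosphorylation, cell cycle, immediate early and heat shock, unfolded protein and integrated stress, cholesterol, oxidative stress and housekeeping genes. Of their 457 members, 6 were found under an older symbol and 4 were not matched. After the values were seen, 8 further lists were added, and their results stand only in the closing section.

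Genes were named by rule. They were, for each CSGG comparison the 12 highest and 12 lowest log2 ratios among genes with at least 5 FPKM in the higher library, 12 and 12 by the smaller of both ratios where the sign was shared, 8 and 8 for each mock comparison, up to 4 members of each list by their mean log2 ratio over both times, and 9 genes of tolerance and costimulation. The ranked part left out symbols beginning with Mir or Snor, predicted genes (Gm with a number, or ending in Rik), pseudogenes marked ps, and immunoglobulin and T cell receptor segments. The rule reads symbols only, so the small nucleolar RNA Rnu3b4 stayed in. Coordinates are 1-based and from GENCODE M21, which uses the same build, GRCm38, as mm10.

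FPKM carries no total depth, but low values moved in whole steps. The ratios of low values to those of mock 0 h lay within 0.03 log2 of ratios of small whole numbers for 82.9%, 83.6%, 82.6% and 72.9% of low genes in mock 4 h, CSGG 4 h, mock 8 h and CSGG 8 h. They gave relative fragments per FPKM of 1.03, 0.740, 1.01 and 0.690, which are relative depths only if no further scaling between libraries was applied. With transcript lengths of GENCODE M21 the steps gave approximate fragments per gene and 95% Clopper-Pearson intervals of each ratio, for transcripts of at least 300 nucleotides. A count of 3 fragments, the upper limit that a count of 0 allows, is worth 0.249 FPKM on 1 kb in mock 0 h and 0.361 in CSGG 8 h. Intervals cover counting error only and are approximate, since the counted transcript lengths are not known.

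The steps were tested on simulated data before use. In a simulation of mock 8 h against mock 4 h over 11381 genes, normal noise was drawn with the central spread of the real pair. The size rule called 6.00% of 50 genes changed 1.5-fold, 78.0% changed 3-fold, 94.0% changed 4-fold and 100% changed 8-fold, and 0.751% of unchanged genes. In the real pair 3.62% of genes passed the rule, so its tails were wider than those simulated. That share also holds any change from 4 h to 8 h. In the same simulation, 4 of 100 unchanged lists of 15 genes were called, and 99 of 100 lists shifted by 0.5 log2. Noise shared by the genes of a list was not simulated, so these shares cannot give an error rate for the real lists. The SD of log2 ratios across genes was 0.527 in the real mock pair and 1.33 for CSGG 8 h against mock 8 h. The share of shifted lists called therefore does not carry over to the 8 h comparison. In the real pair, where any change from 4 h to 8 h also counts, 4 gene lists were higher, 5 lower and 17 within. The alternatives fixed with them were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, scaling to the same sum, median of ratios or upper quartile scaling, leaving out repeated symbols, leaving out immunoglobulin, T cell receptor, hemoglobin and mitochondrial genes, thresholds of 1.5-fold and 3-fold, and a threshold at the 99 percentile of the mock pair in 10 expression bins. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.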

Results

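Gene expression was measured by RNA-seq in splenic dendritic cells of C57BL/6 mice, the antigen-presenting cells that prime T cells, after mock treatment or exposure to CSGG. From knowledge of the study, CSGG is a polysaccharide preparation from the cell surface of Bifidobacterium bifidum, a gut bacterium, and the series asks how such polysaccharides lead to regulatory T cells. There were 5 libraries: mock at 0 h, mock at 4 h, CSGG at 4 h, mock at 8 h and CSGG at 8 h. Each group was 1 library, so no difference below has a replicate check, no p-value is given, and counts rest on a fixed rule of size. Values are read as FPKM. Log2 ratios are of FPKM + 1, which understates the change of genes with low values. Values called ratios without log2, and their counting intervals, are of plain FPKM without the added 1. Both compare libraries rather than conditions.

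Each library listed 26665 gene symbols, of which 16321 (mock 0 h), 16313 (mock 4 h), 15526 (CSGG 4 h), 16209 (mock 8 h) and 14511 (CSGG 8 h) were above 0. The 11381 genes with a mean of at least 1 FPKM were analysed. Steps between low values put the worth of 1 fragment on a 1 kb transcript at approximately 0.083 FPKM for mock 0 h, 0.0805 for mock 4 h, 0.112 for CSGG 4 h, 0.0824 for mock 8 h and 0.120 for CSGG 8 h. The CSGG libraries therefore had fewer fragments per FPKM, 0.740 and 0.690 times that of mock 0 h. These are relative depths only if no further scaling between libraries was applied, which is not known. Mir5105, a microRNA symbol, had the highest value in every library and took 28.6%, 43.6%, 72.9%, 31.0% and 68.2% of summed FPKM in mock 0 h, mock 4 h, CSGG 4 h, mock 8 h and CSGG 8 h. Scaling each library to the same sum therefore moved the median log2 ratio of all genes to -1.10 at 4 h and -1.69 at 8 h, against -0.00 and -0.08 with the deposited values. All directions below are for the deposited values, relative to those medians near 0, and many turn under that scaling.

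After 4 h, the CSGG library had far higher values of inflammatory cytokine and chemokine genes than the mock library. Ccl4, a chemokine that attracts T cells and monocytes (chromosome 11, 83662584 to 83664683, mm10), stood at 13.2 FPKM in mock and 690 in CSGG, a ratio of 52.1 (approximate 95% counting interval 42.9 to 63.4). Its neighbour Ccl3 (chromosome 11, 83647844 to 83649355) stood at 8.64 FPKM in mock and 298 in CSGG, a ratio of 34.5 (27.7 to 43.6). In mock 0 h, Ccl4 stood at 190.2 and Ccl3 at 142 FPKM. The ratios of both genes at 4 h and 8 h therefore also hold lower values in cultured mock than at 0 h. Il6, a proinflammatory cytokine, stood at 1.30 and 42.9 FPKM, with a ratio of 33.0 (23.7 to 46.7). Ptgs2, the inducible enzyme of prostaglandin synthesis, stood at 1.43 and 44.6 FPKM, with a ratio of 31.2 (25.0 to 39.7). Ifnb1, which encodes interferon beta (chromosome 4, 88522025 to 88522774), was near the floor in mock at 0.126 FPKM, or 1 fragment. In CSGG it stood at 60.2 FPKM, so its ratio of 478 has an interval from 100 to 2.22e+04. Rsad2, an antiviral gene induced by interferon, stood at 13.2 and 226 FPKM. Areg, a growth factor of the EGF family, stood at 0.361 and 18.9 FPKM, and Chac1, a glutathione-degrading enzyme induced by amino acid stress, at 4.22 and 75.2 FPKM.

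The other genes among the 12 highest at 4 h encode structural RNAs of the spliceosome, ribosome or RNA processing enzymes, and the small nucleolar RNA Rnu3b4. Rn5s20 (88.7 FPKM), Rnu2-10 (64.2) and Rnu3b4 (15.4) were listed at 0 in mock 4 h. Rn5s20 was listed at 0 in all other libraries too, CSGG 8 h included. Rpph1 stood at 19.7 and 343 FPKM. These RNAs are very short or lack a poly(A) tail, so their FPKM is uncertain. Among the 12 lowest, Siglech, a receptor of plasmacytoid dendritic cells, stood at 32.5 FPKM in mock and 4.55 in CSGG, a ratio of 0.140 (0.111 to 0.173). Cd209a, a lectin of conventional dendritic cells, had a ratio of 0.0692 (0.0241 to 0.15), from 6.80 to 0.471 FPKM. Klrd1, which encodes the receptor CD94, stood at 51.5 FPKM in mock and 9.20 in CSGG, a ratio of 0.179 (0.138 to 0.227). The log2 ratios of the rest were -2.46 for N4bp2l1, -2.41 for Pde1b, -2.34 for Arl6ip4, -2.32 for Tifab, -2.31 for Cd300c, -2.29 for Clec4a3, -2.26 for Dnase1l1, -2.25 for Bzrap1 and -2.18 for Tnnt2.

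At 4 h, 577 genes were at least 2-fold higher and 605 at least 2-fold lower in CSGG than in mock, or 10.4% of the 11381 genes. Of these 1182 genes, 1089 also had a counting interval that excluded a ratio of 1. Between the cultured mock libraries, 8 h against 4 h, 412 genes, or 3.62%, were apart, a number that also holds any change over that time. Both mock libraries had more fragments per FPKM than CSGG 4 h, so the pair is not a matched background. A pseudocount of 5 gave 335 higher and 127 lower genes, and a threshold drawn from the mock pair gave 256 higher and 113 lower. A 3-fold threshold gave 190 and 88, and a mean of at least 5 FPKM gave 474 and 343, so the near-even split depends on these choices.

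**Figure D1:**
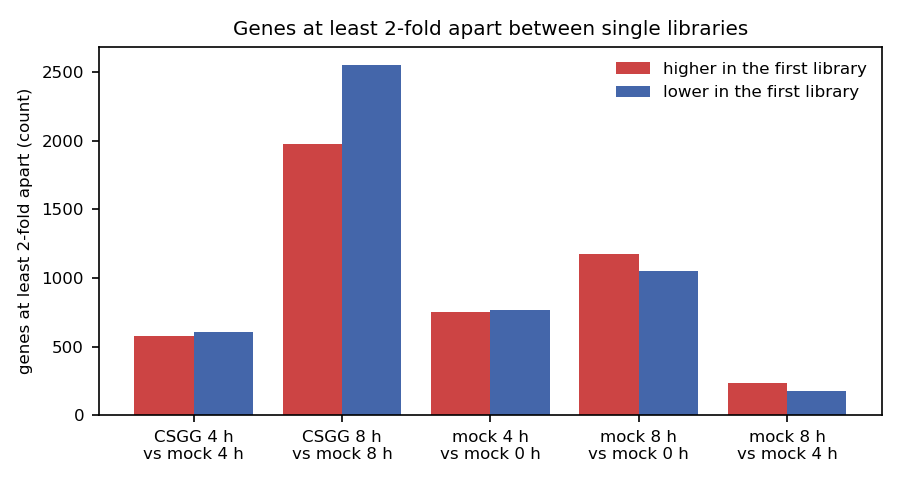
Number of analysed genes (y axis, count) at least 2-fold higher (red) or lower (blue) in the first-named library of each comparison (x axis), with 1 library per group. The bars of CSGG 8 h against mock 8 h stand at 1981 and 2558, and those of mock 8 h against mock 4 h at 237 and 175.

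Among the gene lists, 12 of 26 had a median at 4 h above the central 95% of random lists matched on expression, 2 lay below it and 12 within. Of the 16 measured proinflammatory cytokine genes, 10 were at least 2-fold higher and 0 lower (median log2 ratio 1.96). The largest ratios were those of Ifnb1, Il6, Osm (1.52 to 34.6 FPKM) and Tnf (22.2 to 230 FPKM). Of 16 chemokine genes, 7 were higher and 1 lower (median 0.83). In addition to Ccl3 and Ccl4, Cxcl10 stood at 17.4 FPKM in mock and 244 in CSGG, and Cxcl2, a neutrophil attractant, at 14.2 and 137. Of 30 interferon-stimulated genes, 14 were higher and 0 lower (median 0.94). The log2 ratio was 3.49 for Ifit2, 3.18 for Cmpk2 and 2.88 for Ifit1; the Ifit genes have close relatives whose reads may be shared.

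Stress and metabolic lists were also above random lists at 4 h. Of 14 genes of the unfolded protein and integrated stress responses, 10 were higher and 0 lower (median 1.28). Asns, which makes asparagine, stood at 5.61 FPKM in mock and 64.8 in CSGG, Trib3 at 3.94 and 60.3, and Hspa5, the chaperone of the endoplasmic reticulum, at 156 and 604. Of 18 genes of cholesterol synthesis, 14 were higher and 0 lower (median 1.53), among them Cyp51 (log2 ratio 1.74), Sc4mol (1.92), Insig1 (1.60) and Fdft1 (1.66). The oxidative stress and metallothionein list had 7 of 12 genes higher and 0 lower (median 1.07). Log2 ratios were 1.93 for Hmox1, which degrades heme, 2.58 for Mt2, 1.19 for Gclm and 1.21 for Txnrd1. The immediate early and heat shock list had 8 of 17 higher and 0 lower (median 0.87). The glycolysis and hypoxia list had 6 of 20 higher and 0 lower (median 0.46), led by Vegfa (1.79), Pfkp (1.51) and Hk2 (1.32). The lists of NF-kB targets (median 0.16, 2 of 25 higher and 0 lower), oxidative phosphorylation (0.16), cell cycle (-0.27), pattern receptors (-0.15), MHC class I (0.07), MHC class II (0.21) and housekeeping genes (0.15) lay within random lists. With the GC content and length trend removed, the cell cycle list was below them (-0.34).

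**Figure D2:**
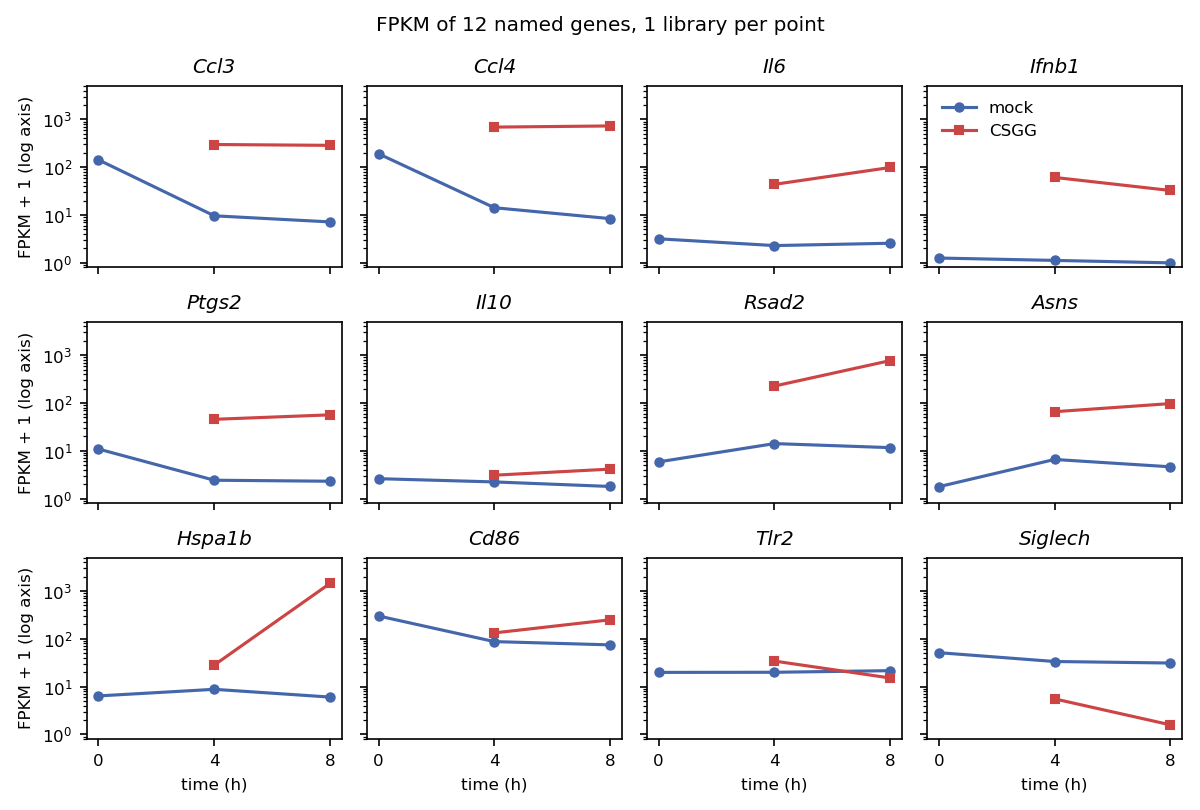
FPKM + 1 (y axis, log scale) against time in hours (x axis) for 12 named genes, with mock in blue and CSGG in red. Each point is 1 library and lines only join the points of a treatment; Ccl4 stood at 690 and 729 FPKM in the CSGG libraries and at 13.2 and 7.42 in mock.

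At 8 h, Hspa1b, Hspa1a and Ccl4 were the protein-coding genes among the 12 highest. Hspa1b, an inducible HSP70 chaperone (chromosome 17, 34956436 to 34959238), stood at 5.05 FPKM in mock and 1444 in CSGG, a ratio of 286 (246 to 334). Its near-identical copy Hspa1a stood at 5.70 and 1155 FPKM, and reads of the pair may be shared. Ccl4 stood at 7.42 and 729 FPKM, a ratio of 98.3 (76.6 to 130.2). The other genes among the 12 highest encode structural RNAs. Rny1, Rnu5g, Scarna3a and Scarna8 were listed at 0 in mock 8 h and at 3622.5, 1807, 240 and 79.9 FPKM in CSGG. Rnu1a1, Rnu1b6, Vaultrc5, Rnu2-10 and Rmrp had log2 ratios of 8.20, 8.22, 7.31, 7.17 and 6.60. Among the 12 lowest were Adam11, a membrane protein of the ADAM family (chromosome 11, 102761439 to 102780262), at 87.2 FPKM in mock and 0.422 in CSGG, a ratio of 0.00484 (0.00288 to 0.0077). Uba7, the enzyme that activates ISG15, stood at 113 and 3.40. Card9, an adaptor of C-type lectin receptors, stood at 69.7 and 2.34 FPKM, Siglech at 30.2 and 0.588, and Spib, a transcription factor of plasmacytoid dendritic cells and B cells, at 120 and 6.22. The log2 ratios of the rest were -5.32 for Tbc1d10c, -4.37 for Ptk6, -4.15 for Haghl, -4.15 for Apol7c, -4.14 for Izumo4, -4.13 for Rogdi and -4.13 for B3gat3, with Ptk6 and Izumo4 listed at 0 in CSGG 8 h.

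At 8 h, 1981 genes were at least 2-fold higher and 2558 at least 2-fold lower in CSGG, or 39.9% of those analysed, and 4266 of these 4539 also had a counting interval that excluded 1. Across genes, the Spearman correlation of FPKM was 0.788 between CSGG 8 h and mock 8 h, against 0.928 at 4 h and 0.961 between the cultured mock libraries. Log2 ratios at 8 h also followed base composition: the median was 0.42 in the tenth of protein-coding genes with the lowest GC content and -0.99 in the tenth with the highest. These medians were 0.16 and -0.25 at 4 h and 0.11 and -0.05 between the cultured mock libraries. A pseudocount of 5 gave 1382 higher and 1206 lower genes at 8 h, 2588 in all, and a mean of at least 5 FPKM gave 1598 and 1589, so the larger number of lower genes depends on these choices.

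Interferon-stimulated genes stood out at 8 h, when 28 of 30 were at least 2-fold higher and 0 lower (median 2.63). Rsad2 stood at 10.7 FPKM in mock and 771 in CSGG, Ifit2 at 5.30 and 300.1, Cmpk2 at 3.10 and 165 and Ifit1 at 7.38 and 217. In the immediate early and heat shock list, 15 of 17 were higher and 0 lower (median 3.33). They included Atf3 (35.9 to 727 FPKM) and Egr1 (7.45 to 164 FPKM), both transcription factors of the early stress response. The oxidative stress list had 11 of 12 higher and 0 lower (median 2.57), with Hmox1 at a ratio of 9.80 (9.65 to 9.95) and log2 ratios of 3.04 for Gclm and 2.64 for Txnrd1. Medians were 2.07 for proinflammatory cytokines (9 of 16 higher, 1 lower), 1.76 for the stress response list (11 of 14 higher, 2 lower), 1.39 for glycolysis and hypoxia (13 of 20 higher, 1 lower), 1.31 for cholesterol synthesis (12 of 18 higher, 1 lower) and 1.08 for chemokines (8 of 16 higher, 2 lower). The chemokine call was lost with a pseudocount of 5 (median 0.54), with a mean of at least 5 FPKM, and with the GC content and transcript length trend removed.

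Genes with high expression had positive log2 ratios at 8 h, so random lists matched to such genes lay above 0. Against these, the MHC class II list was lower (median -0.55, 1 of 14 higher and 6 lower). Ciita, the transactivator of class II genes, stood at 56.2 FPKM in mock and 5.17 in CSGG and H2-Eb2 and Ifi30 at 79.4 and 1144 FPKM in mock and 14.5 and 497 in CSGG, while the abundant H2-Aa was higher (1.04). The NF-kB list was lower with a median of -0.11, yet its mean was 0.14 and 4 members were higher against 3 lower, among them Rel (2.60), Nfkbiz (1.77), Sod2 (1.70) and Tnfaip2 (-1.47). The MHC class I list was lower with a median of -0.10 and a mean of 0.01, with Pdia3 at 1.44, Calr at 1.28, B2m at 0.85 and Psmb9 at -1.60. Removing the GC content and length trend ended the calls of the NF-kB and MHC class I lists and turned their medians to 0.26 and 0.34. Oxidative phosphorylation (0.48), pattern receptors (-0.03), cell cycle (-0.25) and housekeeping genes (0.40) lay within random lists, though single members moved far. Cycs, cytochrome c, had a log2 ratio of 2.12, Cox7a2 1.49 and Atp5b 1.10. The mitotic genes Birc5, Aurkb, Plk1 and Ccnb1 had -1.82, -1.81, -1.44 and -1.46. The receptors Tlr13, Tlr11 and Tlr12 had -2.13, -1.89 and -1.21, and the lysosomal enzyme Gusb had -1.49.

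**Figure D3:**
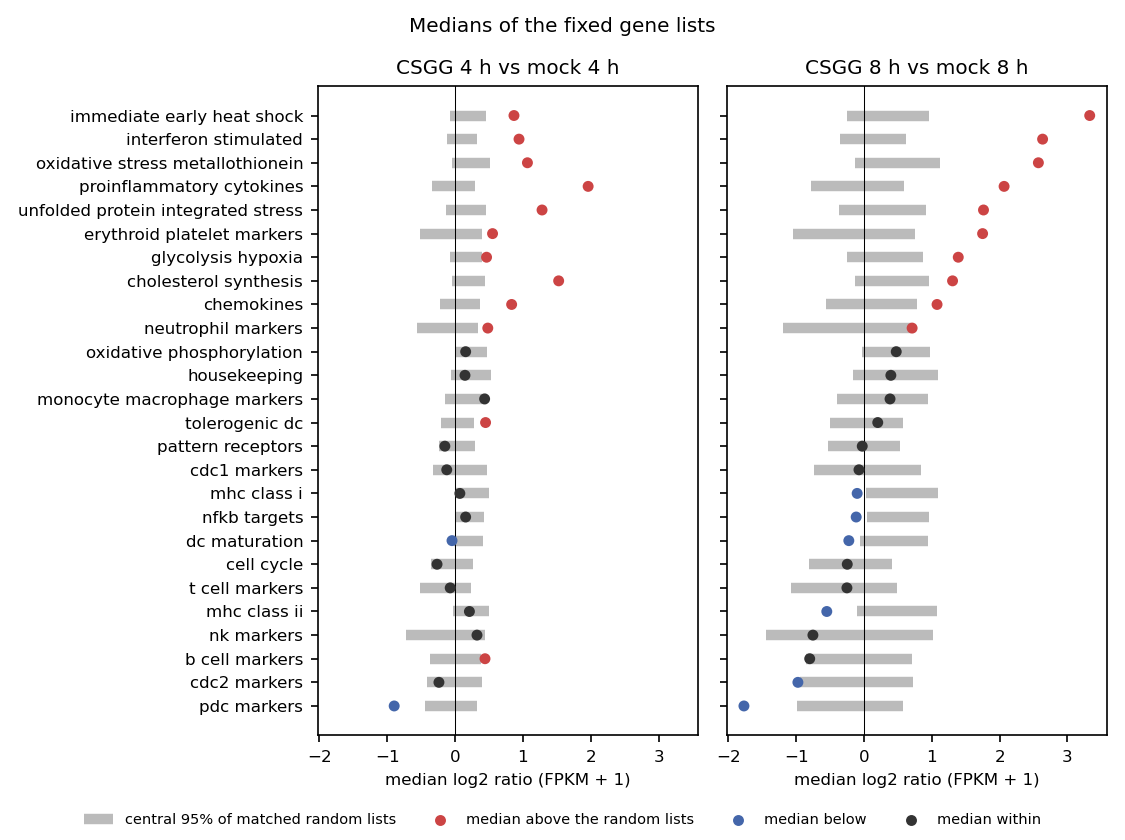
Median log2 ratio of FPKM + 1 (x axis) of each of 26 gene lists (y axis) at 4 h (left) and 8 h (right), with the central 95% of matched random lists as grey bars. Red points lie above the bar, blue below and black within; plasmacytoid markers (pdc) stood at -0.90 and -1.77, and interferon-stimulated genes at 0.94 and 2.63.

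The comparisons at 4 h and 8 h share no library. Of the genes at least 2-fold higher at 4 h, 470 were also at least 2-fold higher at 8 h, against 100.4 for independent lists. A further 491 were lower at both times, against 136 for independent lists. Only 6 genes were higher at 4 h and lower at 8 h, and 3 the reverse. Across the 11381 genes, which are not independent replicates, log2 ratios at the 2 times correlated with Pearson r = 0.66 and Spearman rho = 0.73, 77.6% had the same sign, and the SD across genes was 1.82 times as large at 8 h. The genes highest at both times were Rnu2-10, Ccl4, Ifnb1, Ccl3, Il6, Ptgs2, Rpph1, Rnu3b4, Rsad2, Areg, Rnu1a1 and Cxcl10. In the 8 h libraries Il6 stood at 1.57 FPKM in mock and 97.9 in CSGG, Ptgs2 at 1.31 and 55.6, Ccl3 at 6.19 and 286 and Cxcl10 at 9.95 and 241, and Ifnb1 was listed at 0 in mock and at 31.6 in CSGG. The genes lowest at both times were Siglech, N4bp2l1, Pde1b, Klrd1, Arl6ip4, Tifab, Clec4a3, Cd300c, Dnase1l1, Cd209a, Rnf166 and Tmem86a, with log2 ratios at 8 h from -2.25 (Cd209a) to -4.30 (Siglech).

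**Figure D4:**
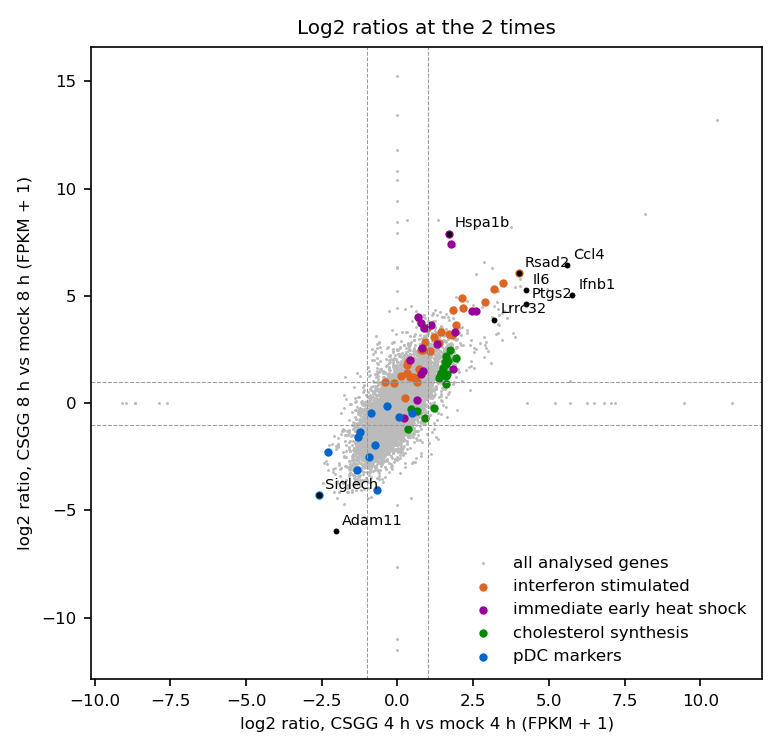
Log2 ratio of FPKM + 1 at 4 h (x axis) and 8 h (y axis) for the 11381 analysed genes (grey), with 4 gene lists coloured and 9 genes named. Dashed lines mark a log2 ratio of 1 in either direction; Pearson r across genes was 0.66, and the points far out on the axes are genes listed at 0 in some libraries, mostly small RNAs.

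Genes tied to tolerance and to T cell stimulation were read out separately, since the series concerns regulatory T cells. Il10, an anti-inflammatory cytokine, was low throughout: it stood at 1.24 FPKM in mock 4 h and 2.09 in CSGG 4 h, a ratio of 1.69 whose counting interval (0.886 to 3.19) includes 1, and at 0.799 and 3.15 FPKM at 8 h, a ratio of 3.94 (1.96 to 7.88). Tgfb1 had a ratio of 1.35 (1.28 to 1.42) at 4 h and 0.848 (0.790 to 0.909) at 8 h. Tlr2, a receptor of bacterial lipoproteins, had a ratio of 1.75 (1.59 to 1.94) at 4 h and 0.688 (0.605 to 0.781) at 8 h. Il12b, which encodes the shared subunit of IL-12 and IL-23, had ratios of 1.06 (0.935 to 1.21) and 1.28 (1.12 to 1.46). Cd274, the inhibitory ligand PD-L1, had ratios of 2.11 (2.04 to 2.18) and 3.08 (2.99 to 3.16). Among costimulatory genes, the ratios at 4 h and 8 h were 2.27 and 2.78 for Cd80, 1.53 and 3.38 for Cd86, and 0.580 and 0.458 for Cd40. In mock 0 h, Cd80 stood at 86.84, Cd86 at 299.3 and Cd40 at 24.81 FPKM. At 4 h and 8 h, Cd86 was below its 0 h value in CSGG (131.9 and 248.97 FPKM) and lower still in mock (86.44 and 73.72). Cd40 was above its 0 h value in mock (106.85 and 58.30 FPKM) and in CSGG (61.99 and 26.69). Cd80 was below it in mock (56.1 and 56.66 FPKM) and above it in CSGG (127.1 and 157.2). These 3 genes' ratios therefore also hold changes in mock since 0 h. All these intervals cover counting error only.

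The tolerogenic list of 26 measured genes had 8 higher and 3 lower at 4 h (median 0.45, above random lists, a call lost with a pseudocount of 5) and 10 higher and 7 lower at 8 h (median 0.20, within). Its members went both ways: Ptgs2 and Hmox1 were higher at both times, whereas the tryptophan-degrading enzymes Ido1 (4.79 to 0.446 FPKM at 4 h, 27.7 to 1.18 at 8 h) and Ido2 (log2 ratios of -2.00 and -3.65) were lower. The maturation list had 4 of 20 higher and 1 lower at 4 h, with a median of -0.05, a mean of 0.11 and a call of lower against random lists, which ended with the GC content and length trend removed and with scaling to the same sum. At 8 h, 4 were higher and 6 lower (median -0.22, lower than random lists). Its members Tnfsf4 and Cflar had log2 ratios of 1.06 and 1.31 at 4 h and 2.33 and 1.51 at 8 h, and Slco5a1 and Cacnb3 had -1.16 and -0.51 at 4 h and -2.86 and -2.56 at 8 h.

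Markers of cell types that a splenic dendritic cell preparation can hold did not move together. Plasmacytoid markers were lower at both times: 5 of 12 were at least 2-fold lower at 4 h (median -0.90) and 8 of 12 at 8 h (median -1.77). At either time 0 were higher. Besides Siglech and Spib, Klk1 stood at 13.6 FPKM in mock and 4.76 in CSGG at 4 h, and at 7.58 and listed at 0 at 8 h, and Cd300c had a log2 ratio of -2.31 at 4 h. Markers of conventional type 2 dendritic cells had 4 of 11 lower at 4 h (median -0.24, within random lists) and 5 of 11 lower at 8 h (median -0.97, lower, a call lost with a pseudocount of 5, with no filter, with scaling to the same sum and with the GC content and length trend removed). Cd209a, Clec10a, Clec4a4 and Sirpa had log2 ratios of -2.41, -1.06, -1.12 and -1.06 at 4 h and -2.25, -1.64, -1.58 and -1.57 at 8 h. Type 1 markers lay within random lists (medians -0.12 and -0.07) with members in both directions, Xcr1 at 2.86, Batf3 at -3.51, Cd8a at -2.75 and Clec9a at -1.50 at 8 h.

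B cell markers were higher at 4 h (median 0.44, 1 of 12 at least 2-fold higher, a call lost at a mean of at least 5 FPKM) and within random lists at 8 h (-0.80, 3 lower; below them with a pseudocount of 5), with Ms4a1 at 0.76 and 0.24. T cell (-0.07 and -0.25), NK cell (0.32 and -0.75) and monocyte and macrophage markers (0.44 and 0.38) lay within random lists. The NK list at 4 h was above random lists with no filter (median 0.22), with scaling to the same sum (-0.33) and with the GC content and length trend removed (0.40). Among their members were C1qc at 1.28 and 1.33, Ccr2 at -1.62 and -1.32, Ly6c2 at -0.95 and -1.89, Mertk at -0.58 and -1.94, Cd8b1 at -0.58 and -1.83 and Klre1 at -0.50 and -1.75. Erythroid and platelet markers were higher at both times (medians 0.55 and 1.75, 2 and 6 of 9 higher). The hemoglobin genes Beta-s, Hba-a1 and Hba-a2 stood at 14.2, 13.1 and 7.96 FPKM in mock 8 h and 77.7, 49.8 and 45.3 in CSGG 8 h, and the platelet gene Pf4 at a log2 ratio of 2.56; the hemoglobin copies share reads. Neutrophil markers were higher at both times (0.48 and 0.71, 1 and 3 of 8 higher, 0 and 2 lower). The 4 h call ended with a pseudocount of 5 and the 8 h call with a pseudocount of 0.1, with no filter, with scaling to the same sum and with the GC content and length trend removed. Cxcr2, S100a8 and Lcn2 had log2 ratios of 2.95, 1.69 and 1.32 at 8 h, and Csf3r -1.36.

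The mock libraries also differed among themselves, in lists that partly match those of the CSGG comparisons. Between 0 h and 4 h, mock cells had 14 of 20 maturation genes at least 2-fold higher and 1 lower (median 1.62), 14 of 18 cholesterol genes higher (1.35), and 16 of 30 interferon-stimulated genes higher and 1 lower (1.09). They also had 6 of 12 oxidative stress genes higher and 1 lower (1.01), and NF-kB targets higher (0.74). MHC class II genes were lower, 9 of 14 (median -1.47), as were 9 of 14 monocyte and macrophage markers (-1.51), and 3 of 5 NK markers (-1.12). Also lower were type 1 (-0.89), type 2 (-0.47) and plasmacytoid dendritic cell markers (-0.46), erythroid (-0.81) and neutrophil markers (-0.59), proinflammatory cytokines (-0.38), chemokines (-0.28), pattern receptors (-0.54), stress response (-0.54) and immediate early genes (-0.44). The chemokine call was lost with a pseudocount of 5, with no filter, at a mean of at least 5 FPKM and with scaling to the same sum, and the cytokine and type 2 calls with a pseudocount of 5. The erythroid call was lost at a mean of at least 5 FPKM. The highest genes were Nqo1, a quinone reductase (2.04 to 138 FPKM), Cxcl3 (1.47 to 71.5), Il4i1 (72.4 to 1517), Lad1 (9.58 to 189), Socs2 (8.36 to 150.1), Apol7c (36.5 to 570.5), Ahrr (log2 ratio 3.81) and Gca (3.41). The lowest were Il1r2, the decoy receptor of interleukin 1 (688 to 35.7 FPKM), Ccl3 (142 to 8.64), Ccl4 (190.2 to 13.2), Sirpb1a, Ppt1 (237 to 17.8), Tm6sf1, Emilin2 and Fosb (58.7 to 4.45). In total 753 genes were at least 2-fold higher and 769 lower.

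By 8 h in mock culture 1173 genes were at least 2-fold higher and 1049 lower than at 0 h, a comparison that shares the 0 h library with the previous one. Maturation genes (median 2.21, 15 of 20 higher and 1 lower), cholesterol (1.64) and interferon-stimulated genes (1.03) were again higher, as were chemokines (median 0.83, mean -0.20, 4 of 16 higher and 3 lower, a call lost with a pseudocount of 5 and with no filter) and MHC class I genes (0.70). MHC class II (-1.42), monocyte and macrophage (-1.22), NK (-1.23), erythroid (-1.32), type 1 (-1.05), type 2 (-0.50), plasmacytoid (-0.70), pattern receptor (-0.51), glycolysis (-0.36) and immediate early genes (-0.87) were lower. The type 2 call was lost with a pseudocount of 5 and at a mean of at least 5 FPKM, and the glycolysis call with a pseudocount of 5 and with the GC content and length trend removed. Socs2 stood at 234 FPKM, Apol7c at 1046, Ahrr at 50.2, Il4i1 at 1434 and Nqo1 at 59.3. Ido1 stood at 27.7 FPKM against 0.385 at 0 h and Apol10b at 26.5 against 0.375; Rnu11, a spliceosomal RNA, was listed at 0 at 0 h and at 152 FPKM at 8 h. Lowest were Il1r2 (20.7 FPKM), Fosb (0.974), Ccl4, Cxcl9 (28.7 to 0.465), Ccl3, Ppt1 (11.4), Tnfsf14 and Nr4a1 (361 to 26.0).

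From 4 h to 8 h the mock libraries differed least, with 237 genes higher and 175 lower. Gbp2, an interferon-induced GTPase (9.17 to 61.7 FPKM), Gnmt (3.81 to 29.7), Asprv1 (14.5 to 89.5), Ear2 (14.7 to 90.6), Insl6 (log2 ratio 2.52), Adam11 (16.3 to 87.2) and Tm4sf5 (9.94 to 54.0) were highest together with Rnu11. Cbr3 (22.7 to 2.97), Gpr31c (log2 ratio -2.29), Rgs9, Leprel1, Lrrc32 (7.04 to 0.758), Procr (185 to 41.2), Dcstamp and Jdp2 (71.2 to 15.6) were lowest. Oxidative stress genes were lower (median -1.21, 8 of 12 lower), as were chemokines (median -0.54, mean -0.08, 4 of 16 higher and 3 lower), type 1 markers (-0.48, a call lost with no filter and with scaling to the same sum), immediate early genes (-0.45) and erythroid markers (-0.57). Maturation (0.42), MHC class I (0.38), MHC class II (0.25) and cholesterol genes (0.24) were higher. Adam11, among the highest in this mock comparison, was the lowest gene of CSGG 8 h against mock 8 h, and both comparisons use the mock 8 h library.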

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

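Of the tests in this part, that of the GC content and length trend on the plasmacytoid markers was written before its result was seen and the others after.

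Some results differed in sign between the times, which was not tested, as each time has 1 library per group. The difference of the median log2 ratio, 8 h minus 4 h, was -1.24 for B cell markers (0.44 and -0.80), -1.08 for NK markers (0.32 and -0.75), -0.76 for MHC class II (0.21 and -0.55), -0.27 for NF-kB targets (0.16 and -0.11) and -0.17 for MHC class I (0.07 and -0.10). With the GC content and length trend removed, the 8 h medians of the NF-kB and MHC class I lists were 0.26 and 0.34, above 0 as at 4 h. Among named genes, those at least 2-fold apart at 1 of the times and of opposite sign at the other were Cd22 (0.42 at 4 h and -2.08 at 8 h, a difference of -2.50), Cd79b (0.34 and -1.58, -1.92), Fcer2a (0.15 and -1.10, -1.25), Cd3e (0.05 and -1.46, -1.51), Ear2 (0.34 and -1.25, -1.59), Ahrr (0.15 and -1.27, -1.43) and Rgs9 (-0.82 and 1.03, 1.84). Cd22, Cd79b and Fcer2a are B cell genes, and Cd3e is a T cell gene.

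The 8 h comparison had far more genes at least 2-fold apart than the 4 h comparison, 4539 against 1182. Removing the trend with GC content and transcript length left 3625 genes at 8 h and 935 at 4 h, against 4062 and 1024 of the same protein-coding genes before it, so that trend is not the whole cause, although it held 13.0% of the variance at 8 h. Among genes with a mean of at least 100 FPKM, where depth matters little, 43.2% were apart at 8 h against 13.5% at 4 h and 4.22% in the cultured mock pair. A scale shift from a few abundant RNAs would leave the ranks of genes as they are. Yet the Spearman correlation of CSGG with mock was 0.788 at 8 h against 0.928 at 4 h. Such a shift is therefore not the whole cause, although it sets the counts under scaling to the same sum (8892 and 6625). The test of this shift was replaced repeatedly after its values were seen. A longer exposure to CSGG and a difference in RNA quality or handling of that library both stay open, since CSGG 8 h is 1 library and nothing in the sources used here separates them.

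RNAs of kinds that mostly lack a poly(A) tail were higher as sets in both CSGG libraries. Medians over the 32 histone cluster genes were 1.34 at 4 h and 2.07 at 8 h, with 17 and 25 at least 2-fold higher. The 18 structural RNA genes, with Mir5105 among them, had medians of 1.70 and 6.31, with 11 and 17 at least 2-fold higher. Some, such as Rny1 and Rnu5g, were listed at 0 in both 4 h libraries. This list was made after many of its genes had ranked highest, so its medians describe those genes and test nothing. Replicating cells would raise the cell cycle genes with the histones, but their median at 8 h was -0.25. Histone cluster genes lay 1.69 log2 above other protein-coding genes with transcripts of 300 to 600 nucleotides at 8 h, not beyond the bound of 1 by more than 2 standard errors. At 4 h the median of those 90 other genes was 0.0018, against 1.34 for the histone cluster genes, and no bound was set for that time. With 0 protein-coding genes under 300 nucleotides analysed as well, the length correction stays open for both kinds. The histone bound had been lowered for a while after its value was seen, and the first bound was put back. More RNA without a tail carried into the CSGG libraries is a candidate explanation that these values do not establish. Histone cluster genes lay 2.85 log2 above the replacement histone genes, whose transcripts mostly carry a tail, at 8 h and 1.59 at 4 h. Members of neither list were sorted by whether their own transcripts carry a tail, so some may not match their list. Both lists were taken up after the values were seen. Most replacement genes also had higher values in mock, so tail and expression level are not separated. Tails added in stressed cells to RNAs that normally lack them would give the same values and were not tested.

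Plasmacytoid markers were lower at both times, with medians of -0.90 and -1.77. With the GC content and length trend removed, the median at 4 h was -0.88, below each of the random lists, so that trend is not the cause at 4 h. The test was written for 4 h only, though the call of lower at 8 h was also kept under that setting. Fewer plasmacytoid cells would lower genes restricted to them by the same ratio, yet 9 of the 12 counting intervals at 4 h excluded the median plain FPKM ratio of 0.499. Since other dendritic cells express several of these genes and counting intervals leave out variation between cultures, a loss of cells cannot be told apart from lower expression per cell. The members that differed least, chosen after their values were seen, were Tcf4 (-0.34 and -0.13), Runx2 (0.04 and -0.67) and Cox6a2 (-0.86 and -0.48).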

How the results depend on the processing

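The GC content and length setting, the setting without short and histone transcripts and the counting interval were chosen after seeing the data. The cause of the shifts below was not tested, except where a threshold, a pseudocount or the sum itself sets the count. With 1 library per group, leaving a library out is impossible.

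Of 52 calls of gene lists against random lists in the CSGG comparisons, 40 were the same under each of the settings that gave them a value, as were 64 of 78 in the mock comparisons. Of the values of named genes at 4 h and 8 h, 193 of 350 stayed on the same side of 2-fold under each setting, and 298 of 350 under each but scaling to the same sum. Of the 254 that were at least 2-fold apart, 34 turned in sign. Leaving out repeated symbols moved nothing, as there were 0. Median of ratios and upper quartile scaling, no filter, a mean of at least 5 FPKM, leaving out immunoglobulin, T cell receptor, hemoglobin and mitochondrial genes, leaving out short and histone transcripts, and requiring the counting interval each kept the total counts within 1.5 times. Counted by direction at a mean of at least 5 FPKM, the lower genes moved further, from 605 to 343 at 4 h and from 2558 to 1589 at 8 h. So did the genes lower at both times (491 to 289) and the higher genes of mock 8 h against mock 4 h (237 to 152). At a mean of at least 5 FPKM too few NK and neutrophil markers were left for some calls. Under the GC content and length setting, the correlation between the times moved from 0.66 to 0.76. That setting also kept only 10373 protein-coding genes, so removing the trend and leaving out other genes are not separated.

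The counts moved with the pseudocount and the threshold. A pseudocount of 0.1 gave 1849 genes at 4 h, 1458 at both times and 700 between mock 8 h and mock 4 h. A pseudocount of 5 gave 462 at 4 h, 2588 at 8 h, 385 at both times, and 806, 1206 and 160 for mock 4 h against 0 h, 8 h against 0 h and 8 h against 4 h. In the same order, a 1.5-fold threshold gave 3532, 7057, 2883, 3639, 4609 and 1585 and a 3-fold threshold 278, 2173, 217, 537, 846 and 89. The threshold from the mock pair gave 369 at 4 h, 2581 at 8 h and 300 at both times.

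Scaling to the same sum, which Mir5105 dominates, gave 6625 genes at 4 h, 8892 at 8 h, 6245 at both times and 686 between mock 8 h and mock 4 h. The share of higher genes went from 48.8% to 1.19% at 4 h, from 43.6% to 1.99% at 8 h and from 49.5% to 26.3% for mock 4 h against mock 0 h, and from 57.5% to 85.7% for mock 8 h against mock 4 h. Under it the log2 ratio at 4 h turned, among others, for Beta-s (-0.23), C1qc (-0.0433), Calr (-0.33), Cd274 (-0.27), Cd80 (-0.16), Cflar (-0.0215), Emilin2 (-0.0417), Gclm (-0.14), Gpr31c (-0.0433), Hba-a1 (-0.00239), S100a8 (-0.25), Tnfsf4 (-0.25) and Txnrd1 (-0.13), and at 8 h for Atp5b (-0.95), C1qc (-0.69), Calr (-0.77), Cd274 (-0.43), Cd80 (-0.57), Cd86 (-0.29), Cflar (-0.52), Cox7a2 (-0.53), Emilin2 (-0.43), Fdft1 (-0.057), H2-Aa (-1.01), Hba-a1 (-0.11), Il10 (-0.0375), Nfkbiz (-0.23), Nqo1 (-0.54), Pdia3 (-0.60), Rgs9 (-0.31), S100a8 (-0.24), Sod2 (-0.24) and Ywhaz (-0.53).

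The CSGG libraries had the fewest fragments per FPKM, and low genes carry the widest intervals, such as 1 fragment of Ifnb1 in mock 4 h.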

Other observations

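The lists in this part, and the genes chosen from them, were taken up only after the values were seen. Aminoacyl-tRNA synthetases, which charge transfer RNAs with amino acids, were higher in CSGG at both times, 10 of 21 at least 2-fold at 4 h (median log2 ratio 0.92) and 11 higher and 2 lower at 8 h (1.67). Gars, Cars and Nars had log2 ratios of 1.85, 1.51 and 1.14 at 4 h and 2.40, 2.33 and 2.48 at 8 h, while Qars and Vars had -1.01 and -1.27 at 8 h. The chaperonin CCT, which folds actin and tubulin, lay within random lists at 4 h (median 0.51) and was higher at 8 h (1.41, 7 of 8 at least 2-fold), with Cct3 at 95.5 FPKM in mock and 458 in CSGG. Proteasome subunits lay within random lists at 4 h (0.30) and were higher at 8 h (0.97, 18 of 37 higher and 1 lower). Cytosolic ribosomal protein genes were lower than random lists at 4 h (0.08, 0 of 73 at least 2-fold apart) and within them at 8 h (0.88), and in mock culture they were lower at 4 h (-0.27) and 8 h (-0.54) than at 0 h. Lysosomal enzymes lay within random lists in CSGG (0.06 and -0.07), and in mock culture were lower at 4 h (-0.55) and 8 h (-0.35).

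Lrrc32 encodes GARP, a surface protein that holds latent TGF-beta. It stood at 9.58 FPKM in mock 0 h, 7.04 in mock 4 h and 0.758 in mock 8 h, and at 73.0 and 25.2 FPKM in CSGG 4 h and 8 h. The ratios of CSGG to mock were 10.4 (counting interval 9.32 to 11.5) and 33.3 (24.5 to 46.6). Procr, the receptor of protein C, stood at 185 and 41.2 FPKM in mock 4 h and 8 h and at 319 and 466 in CSGG. Among histone cluster genes, Hist1h1c, Hist1h2bc and Hist2h2be had log2 ratios of -0.73, -0.56 and -0.17 at 8 h, whereas Hist1h4c and Hist1h3a had 4.27 and 5.21. The replacement histone genes were lower than random lists at 4 h (-0.25) and 8 h (-0.78), with 3 of 8 at least 2-fold lower at 8 h.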
